A study of Arabidopsis thaliana with 4 samples.

How the data were processed

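RNA was taken from 5-d-old Arabidopsis seedlings of the Col-0 ecotype grown under constant light at 22 °C, per the labels' protocols; the labels give the tissue as root tip, while the extraction text speaks of roots. The overexpressing line was labelled SCL28-OX. Total RNA was extracted with TRI reagent and cleaned on RNeasy columns, and libraries were made with the TruSeq Stranded mRNA kit, which keeps the strand of the transcript, per the labels' protocols. Whether the authors' counting used the strand is not given in the sources used here. Per the submitters' processing notes, the tools were CASAVA 1.8.2, TopHat2 2.0.13 and Cuffdiff 2.2.0, with the TAIR10 genome.

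The authors deposited FPKM per gene for each of the 4 libraries, per the file headers, and these FPKM values were the starting point for every test here. FPKM divides the fragments of a gene by transcript length and by a measure of library size. A difference between libraries in how fragments are lost from long or short transcripts therefore stays in the values. A second table, the authors' deposited table of the comparison, holds group mean FPKM, the score of the authors' test, and a p-value and q-value per gene, per the file headers. The deposited q-value was used for comparison with the calls made here, and the deposited score was read but gave no printed value. The authors' mean FPKM matched the mean of the 2 libraries within 0.1% for all 26822 lines used. Of 26883 lines, 60 were left out because a space in the gene name had shifted their columns, and 1 is not analysed here. A further 4371 lines were listed at 0 in all 4 libraries.

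Loci were assigned to 26461 lines, from the line's own name or the locus tag of the deposited table where its position fitted, or from symbol and position in the RefSeq annotation of TAIR10.1. Lines that join several loci numbered 287, and 74 lines could not be matched. Positions are those of the deposited table on TAIR10, counted from 1. Because 3043 lines share their interval with another line, reads of overlapping genes may not have been told apart; the counts were repeated without these and the joined lines. A symbol that several loci share was replaced by the locus, since AT5G18810, which encodes an SC35-like splicing factor, is also listed as SCL28 in the deposited table.

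No read counts were used, so count models were not applied. The unit of 1 fragment was read from the steps of low FPKM values in single-transcript genes whose ends equal the annotation. With an effective length of transcript length minus 164 to 167 bases plus 1, 93.7% to 94.6% of the values between 1 and 15 fragments were whole within 0.1. This gave depths of about 33100000, 27600000, 28000000 and 26100000 fragments. These depths follow from the scaling of the FPKM alone and were not checked against counts of mapped fragments. They are depths only if each library was scaled by its own mapped fragments. Few genes have models that allow this, and fragments were not recovered for the rest. In a chi-square test of these fragments over 432 and 426 genes, the libraries of a genotype differed little beyond counting noise, with a chi-square per degree of freedom of 1.22 in WT (p = 0.00103) and 1.24 in SCL28-OX (p = 0.000562). Between genotypes it was 28.4 to 36.8. The excess within genotypes lay in part of the range only. In WT it lay in the 33 genes over 5000 fragments (3.42; chi-square test, p = 5.84e-11), and in SCL28-OX in the 158 genes of 500 to 5000 fragments (1.49; chi-square test, p = 5.5e-05). No other range differed at a p under 0.05. Each library was counted as 1 replicate because both pairs differed over all genes, but a spread this small leaves open that the libraries of a genotype came from 1 RNA pool.

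Genes with a mean of at least 1 FPKM over the 4 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), two-sided, with Benjamini-Hochberg adjustment over the 18087 genes and a threshold of 0.05. A pseudocount of 1 FPKM understates the change of low genes. The 27 gene lists, their test and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists, and again with an estimated correlation and with fry. The text names SCL28, the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap and whose higher mean is at least 5 FPKM, and up to 2 rises and 2 falls per list. SIM, the SMR genes, CYCB1;1, CYCB1;2, KNOLLE and CDKB2;1 could be named in any case. Calls were set against the authors' q-value of 0.05 with Fisher's exact test.

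Alternatives planned before the data were examined were a pseudocount of 0.1 or 5 FPKM, no filter, a minimum mean of 5 FPKM, median-ratio scaling, quantile normalization, eBayes without trend, robust eBayes, the replicate number as a block, and each library left out in turn. The correction for transcript length was added after the data were seen. For each library, the deviation from the mean over the 4 libraries was smoothed with lowess (span 0.3) on the log2 length of the longest annotated transcript and subtracted. Lengths were known for 98.2% of the tested genes. They came from the TAIR10.1 annotation, where 14.6% of the mapped lines had the same start and end as in the deposited table. The lengths behind the FPKM can therefore differ from those used in the correction. Variants used coding length, or length and then GC content, or length with the replicate block.

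The fit was tested on simulated data drawn from the real means, lengths and depths with 200 changed genes. In the simulated comparison of SCL28-OX with WT over 17653 genes, it recovered 66% of changes of 1.25-fold, 88% of 1.5-fold, 100% of 2-fold and 94% of 4-fold, and called 0.0859% of the unchanged genes. With a length trend added, over 17619 genes, 63.4% of the unchanged genes were called without the correction and 0.178% with it, and the correction recovered 68%, 88%, 96% and 98% of the 4 fold sizes. The simulated libraries had an extra coefficient of variation of 2%, and the real data kept a GC trend after the correction (rho = 0.345). The rate of 0.178% is therefore not an estimate of false calls among the real genes. A list shifted in the simulation was the 1 list that camera called. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.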

Results

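Transcripts were measured by RNA-seq in the root tip of 5-d-old Arabidopsis thaliana seedlings of the Columbia ecotype (Col-0). Wild type (WT) was set against a line that overexpresses SCL28, a transcription factor gene of the GRAS family (SCL28-OX). The GRAS family of plant regulators takes its name from GAI, RGA and SCARECROW. Each genotype had 2 libraries, and the values were FPKM, fragments scaled by transcript length and by a measure of library size. The FPKM values summed to 951429 and 945618 in the WT libraries and to 848731 and 849311 in the SCL28-OX libraries. The steps between low values implied a depth of about 33100000 and 27600000 fragments for WT and of 28000000 and 26100000 for SCL28-OX. These are depths only if each library was scaled by its own mapped fragments. By the same steps 1 FPKM stood for 34.8 to 44.2 fragments of a 1500-base transcript. The labels do not say whether the 2 libraries of a genotype came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

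The comparison asks how the root tip transcriptome differed when SCL28 was overexpressed. SCL28 itself (AT1G63100, TAIR10 chromosome 1, 23399391 to 23401367) stood at 6.78 and 7.57 FPKM in the WT libraries and at 2378.06 and 2300.22 FPKM in the SCL28-OX libraries. The mean was 7.18 ± 0.558 FPKM (SD, n = 2) in WT and 2339 ± 55.0 FPKM (SD, n = 2) in SCL28-OX, a ratio of 326. On the log2(FPKM + 1) scale the difference was 8.16 ± 0.04 (SE), with a limma adjusted p of 1.31e-10. The value does not separate transcripts of the resident gene from those of the introduced copy. In the SCL28-OX libraries SCL28 made up 0.276% of the summed FPKM.

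Beyond SCL28, most of the largest rises in SCL28-OX on the log2(FPKM + 1) scale were in genes of extensins, hydroxyproline-rich structural proteins of the cell wall, and their relatives. On that scale GSTF14, a glutathione S-transferase gene, fell most. Of 18087 genes tested, 5911 were higher and 6112 were lower in SCL28-OX at a limma adjusted p under 0.05. Most of these differences were small: 122 genes were higher and 68 lower by at least 2-fold, and after the correction for transcript length described below 112 and 30. These are partly different genes, as only 59 were higher and 27 lower by at least 2-fold in both fits. Without the correction, a pseudocount of 0.1 FPKM gave counts of 212 and 159, and 5 FPKM gave 44 and 20. The median absolute log2 change was 0.25. The 2 libraries differed by a median absolute log2 ratio of 0.051 in WT and 0.053 in SCL28-OX. That spread is small: for genes of 20 to 500 fragments in a pair, neither pair differed beyond counting noise (chi-square test, p = 0.895 over 234 genes in WT and 0.12 over 238 genes in SCL28-OX). If the libraries of a genotype share 1 pool of seedlings, the counts of called genes are too high, as plant-to-plant variation was then not measured. The FPKM of the 2 genotypes did not overlap at 15117 of the tested genes, or 83.6%, where chance gives 33.3% for interchangeable libraries. A difference in preparation between the groups would raise this share too, so it does not measure an effect of the genotype alone.

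The change depended on transcript length. Across the 17760 tested genes with an annotated length, Spearman's rho between the log2 change and the length of the longest transcript was 0.68, over genes, which are not independent replicates. The median log2 change ran from -0.41 in the shortest of 10 equal groups of genes by length, of 120 to 913 bases, to 0.48 in the longest, of 3103 to 16593 bases. Between the 2 libraries of a genotype rho was 0.0415 in WT and -0.0061 in SCL28-OX. With each library corrected for this trend, a step added after the data were seen, 4175 genes were higher and 4009 lower. Of these, 3043 and 3144 were also called in that direction without the correction, while 168 genes went from higher to lower and 251 from lower to higher. The log2 change also rose with GC content (rho = 0.402 across genes), and still did after the length correction (0.345), which therefore leaves a GC trend in place. Length-corrected counts or medians are given for each list below.

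**Figure D1:**
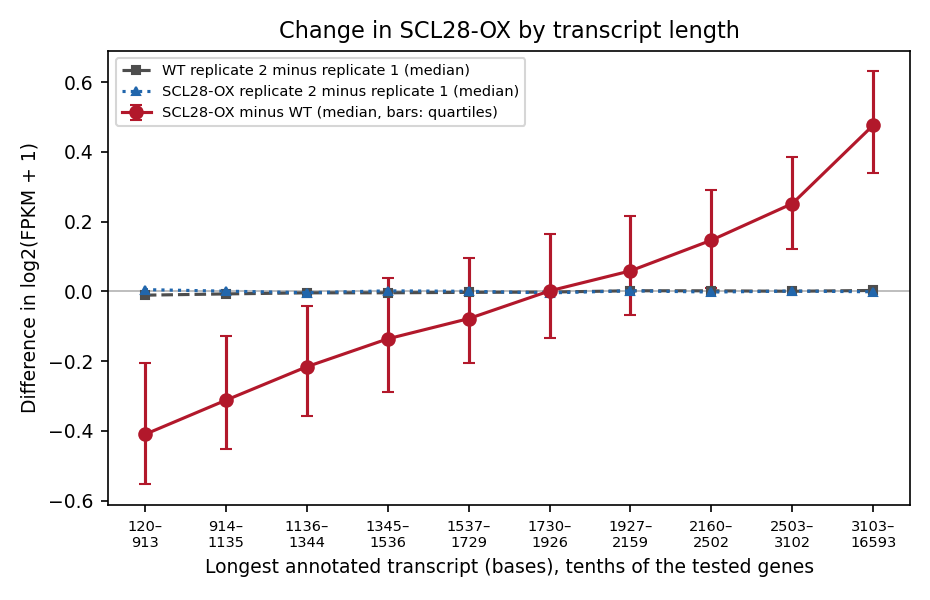
Median difference in log2(FPKM + 1) for 10 equal groups of the tested genes by the length of the longest annotated transcript in bases, with quartiles as bars for SCL28-OX minus WT, and medians for replicate 2 minus replicate 1 within each genotype. The difference between genotypes rises from -0.41 in the shortest group to 0.48 in the longest, while both lines within genotypes stay close to 0.

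Of the 10 genes with the largest rises, 7 encode extensins or related hydroxyproline-rich proteins. EXT12 (AT4G13390, chromosome 4, 7783818 to 7785326) rose from 18.4 ± 2.64 to 87.5 ± 0.697 FPKM (SD, n = 2), a log2 change of 2.198 ± 0.079 (SE; limma adjusted p = 9.33e-07). EXT13 (AT5G35190, chromosome 5, 13434181 to 13435167) rose from 52.3 ± 3.43 to 236 ± 2.75 FPKM (SD, n = 2). The log2 changes of the others were 2.09 for AT3G28550, 2.01 for EXT10, 1.99 for HRGP1, 1.97 for EXT6 and 1.92 for AT4G08410. Only 56.4% of the 50-base words of AT4G08410 occur in no other annotated gene, so its reads may be shared with a near copy, and its value is uncertain. This share was not computed for HRGP1. The other 3 genes were the methyltransferase-family gene AT1G15125 (2.30), the largest rise, the dark-induced and senescence-associated SEN1 (2.11) and AT1G68585 (1.98), which encodes a protein of unknown function. SEN1 (AT4G35770, chromosome 4, 16944941 to 16946192) went from 1.82 ± 0.0916 to 11.2 ± 0.338 FPKM (SD, n = 2). As ratios of mean FPKM, the rises of AT1G15125 (8.53), SEN1 (6.13) and AT1G68585 (5.28), all under 2.5 FPKM in WT, were above that of EXT12 (4.76). After the length correction these 10 log2 changes lay between 1.71 (AT3G28550) and 2.43 (AT1G15125).

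GSTF14 (AT1G49860, chromosome 1, 18458666 to 18459906) fell from 49.5 ± 0.595 to 5.20 ± 0.528 FPKM (SD, n = 2), a log2 change of -3.03 ± 0.06 (SE; limma adjusted p = 2.68e-07) and of -2.80 after the length correction. AT5G64401, a locus of 162 bases, was at 6.85 and 3.99 FPKM in the WT libraries and was listed at 0 in both SCL28-OX libraries. It is shorter than the 164 to 167 bases that the effective length leaves out, so its FPKM and its fall are uncertain. With a pseudocount of 0.1 FPKM it fell more than GSTF14 (-5.74 against -3.23). The glycine-rich protein gene AT2G05510 (-2.31), the defensin-like gene PDF2.1 (-1.88) and the peroxidase gene AT2G41480 (-1.81) also fell. So did the lipid-transfer protein genes AT3G58550 (-1.78) and AT2G18370 (-1.65), IMA2 (-1.75), which encodes a small peptide of the iron deficiency response, and MIF3 (-1.58), a mini zinc finger gene. The combined line of AT5G24240 and AT5G24250, whose reads were not divided between the 2 loci, changed by -2.04. Of these 10, the 8 with a length-corrected value stayed lower, between -2.80 and -1.29; MIF3 and the combined line had no matched transcript length.

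Of 13 tested SIAMESE-type cyclin-dependent kinase (CDK) inhibitor genes, a class that restrains CDKs and promotes endoreplication, 6 rose in SCL28-OX and 4 fell. Those that rose were SIM, from 62.8 ± 4.64 to 88.6 ± 8.74 FPKM (SD, n = 2), SMR1, from 50.2 ± 2.40 to 67.3 ± 3.52, SMR2, from 17.42 ± 1.85 to 34.4 ± 1.38, and SMR8, SMR9 and SMR13 at lower levels. Their log2 changes were 0.49 (SIM), 0.42 (SMR1), 0.95 (SMR2), 0.65 (SMR8), 1.22 (SMR9) and 0.45 (SMR13). The WT libraries of SMR8 differed, at 3.67 and 5.54 FPKM, and its log2 change was 0.41 to 0.89 with each library left out in turn. Those that fell were SMR4 (-0.58), SMR11 (-0.53), SMR3 (-0.32) and SMR6 (-0.25), none of them called lower after the length correction. Over the whole list of CDK inhibitors, 6 of 20 genes rose, 5 fell and 9 did not pass the limma test, with counts of 6 and 5 again when adjusted over the list alone. KRP7 (-0.58) and SMR4 fell furthest, and camera gave the list no direction past its threshold (adjusted p = 0.948). CDK inhibitor transcripts are short, with a median of 1000.5 bases, and so lie in the part of the length range where most log2 changes were negative. After the length correction the 6 genes had log2 changes of 0.72 (SMR13) to 1.53 (SMR9), 9 of the 20 were higher and 1, KRP7, was lower. The camera adjusted p for the list was then 0.0244, or 0.632 with an estimated correlation.

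**Figure D2:**
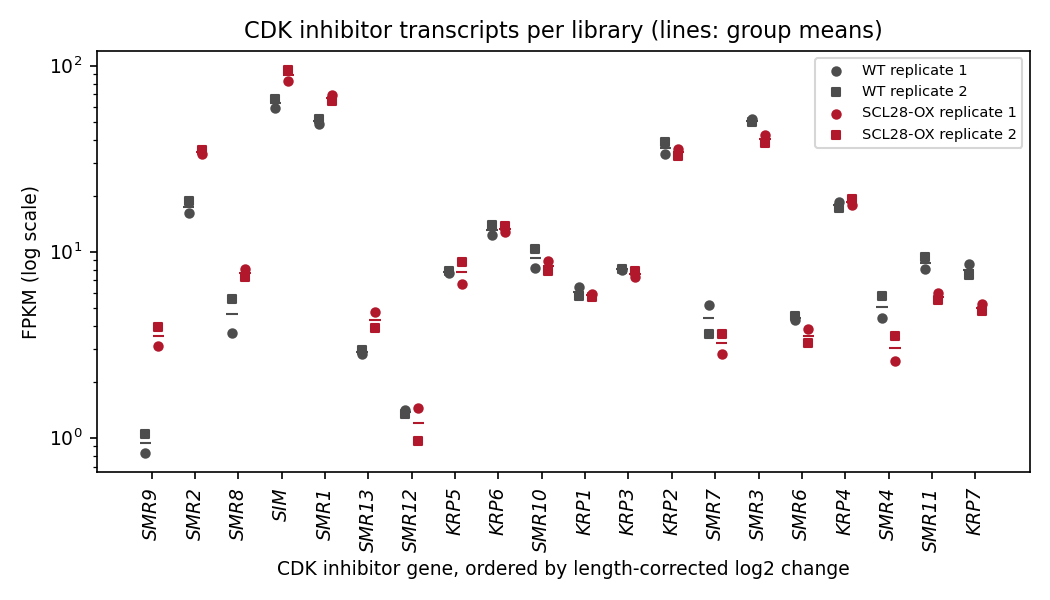
FPKM on a log scale for the 20 tested CDK inhibitor genes in each of the 4 libraries, with short lines at the group means and genes ordered by length-corrected log2 change. SMR9, SMR2, SMR8, SIM, SMR1 and SMR13 stand at the left, with both SCL28-OX libraries above both WT libraries.

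Among the mitotic cyclins and CDKs, 6 of 19 genes rose and 8 fell, and the counts were the same when adjusted over the list alone. CYCB1;1 fell from 14.0 ± 0.255 to 11.2 ± 1.17 FPKM (SD, n = 2) and CYCB1;2 from 28.1 ± 0.498 to 24.6 ± 1.57, log2 changes of -0.30 and -0.18. The call for CYCB1;2 was lost without WT replicate 2 (limma adjusted p = 0.0636) or without SCL28-OX replicate 1 (0.0647), in a range of 0.00333 to 0.0647 with each library left out in turn. CKS2, a CDK subunit gene, had a log2 change of -0.55 and CYCA2;2 one of 0.31, while CDKB2;1 (-0.03) differed by less than the spread between replicates. After the length correction CDKB2;1 was called higher (0.13; limma adjusted p = 0.0424), 4 genes of this list were higher and 6 lower, and CKS2, of 762 bases, was at -0.15, a call lost with the coding length correction (-0.078) and the length and GC correction (-0.053). Of the 25 genes of mitosis and cytokinesis, 15 rose and 7 fell. POK2, a phragmoplast kinesin gene, was at 0.73 and the spindle checkpoint gene MAD2 at -0.43, and KNOLLE, the syntaxin gene of cytokinesis, fell from 68.0 ± 2.04 to 55.7 ± 1.93 FPKM (SD, n = 2; -0.28). These transcripts had a median length of 2379 bases, and after the length correction 3 genes of this list were higher and 7 lower, with POK2 at -0.19 (limma adjusted p = 0.111) and MAD2 at -0.14, whose call was lost with the length and GC correction (-0.075). KNOLLE was at -0.13 after the length correction. Without the correction the 2 lists had camera adjusted p values of 0.588 and 0.406.

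In the list of cell cycle regulators and the endocycle, 10 of 26 genes rose and 4 fell, among them MYB3R1 (0.77), a regulator of G2/M genes, and the D-type cyclin gene CYCD3;3 (-0.61). In the list of DNA replication and the G1/S step, 11 of 27 rose and 5 fell, with the helicase subunit gene MCM7 at 0.61 and the origin recognition gene ORC6 at -0.57. The camera adjusted p values were 0.425 and 0.406. Corrected for length, 5 were higher and 3 lower in the first list, and in the second the balance turned, to 4 higher and 7 lower, with the median going from 0.13 to -0.05. MYB3R1 was then at 0.31, CYCD3;3 at -0.48, MCM7 at 0.39 and ORC6 at -0.34. All 12 genes of the replicative histone list fell, by a median of 0.57 on the log2 scale (camera adjusted p = 2.86e-06, or 0.576 with an estimated correlation). Their transcripts were short, at a median of 734 bases, and after the length correction 8 were lower, 1 was higher and the median was -0.15 (camera adjusted p = 0.00237, or 0.632 with an estimated correlation). In the list of DNA damage genes, 2 of 8 rose and 2 fell (camera adjusted p = 0.977), and none passed the limma test after the length correction.

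Root hair genes were higher as a group. Of 28, 17 rose, 6 fell and 5 did not pass the limma test, again with 17 and 6 when adjusted over the list alone (camera adjusted p = 0.00804, or 0.576 with an estimated correlation). The largest rises were in cell wall protein genes, LRX1 (1.81), a leucine-rich repeat extensin gene, and PRP1 (1.79), a proline-rich protein gene. LRX1 went from 10.6 ± 0.359 to 39.8 ± 0.175 FPKM and PRP1 from 15.3 ± 1.04 to 55.5 ± 2.01 FPKM (SD, n = 2). The cell wall protein gene RHS13 (-0.32) and RSL4 (-0.28), a transcription factor gene of hair growth, fell. After the length correction 19 genes of the list were higher and none lower, with RHS13 at 0.07 and RSL4 at -0.11 (limma adjusted p = 0.0656 and 0.0541). Among 7 genes of non-hair epidermis patterning, GL2 (0.75) and TTG1 (0.66) rose, while WER (-0.68) and CPC (-0.68), a hair-promoting gene, fell. After the length correction GL2 was at 0.47, TTG1 at 0.65, WER at -0.45 and CPC at -0.28. In all, 3 of the 7 rose and 2 fell, with counts of 3 and 2 again after the length correction, though the call for GL2 was lost with the length and GC correction (0.12), and the set test gave a camera adjusted p of 0.741.

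Among the expansin and xyloglucan endotransglucosylase (XTH) genes, which act on wall loosening, 10 of 16 fell and 3 rose. XTH20 fell from 20.5 ± 0.798 to 8.16 ± 0.181 FPKM (SD, n = 2; -1.23) and XTH18 by 0.62 on the log2 scale, while XTH5 rose (0.60). The list's camera adjusted p was 0.0805, and after the length correction 9 were lower and 5 higher. All 7 changes among the 9 genes of the cytokinin response, mostly type-A response regulators, were falls, with ARR7 at -0.86 and ARR9 at -0.60 (camera adjusted p = 0.0348, or 0.696 with an estimated correlation). This list's call was lost without SCL28-OX replicate 1 (camera adjusted p = 0.0747, in a range of 0.00986 to 0.0747 with each library left out in turn). Its median log2 change was -0.37, and -0.24 after the transcript length correction. The list stayed called after that correction (camera adjusted p = 0.0244, or 0.704 with an estimated correlation). Its call was lost with the coding length correction (camera adjusted p = 0.284) and the length and GC correction (0.214).

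Photosynthesis genes, listed as markers of shoot tissue, were higher. Of 18, 12 rose and none fell, or 13 and none when adjusted over the list alone (camera adjusted p = 0.00351, or 0.576 with an estimated correlation). RBCS1A, a gene of the Rubisco small subunit, rose from 19.3 ± 0.409 to 39.3 ± 0.551 FPKM (SD, n = 2; 0.99) and PSAD1, of photosystem I, from 14.7 ± 0.266 to 27.0 ± 1.77 (0.83). The median was 0.37, and 0.46 after the length correction. Of the other GRAS family genes, 14 of 27 rose and none fell, SCL6 (0.79) and the DELLA gene RGL3 (0.59) most, with a camera adjusted p of 0.0144, or 0.576 with an estimated correlation. Their transcripts were long, at a median of 2322 bases, and after the length correction 5 were higher and 3 lower, around a median of -0.00145 (camera adjusted p = 0.663). The call for RGL3 was lost with the length and GC correction (0.23; limma adjusted p = 0.0549).

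Iron deficiency genes moved in both directions: 11 of 21 rose and 9 fell, or 11 and 10 when adjusted over the list alone (camera adjusted p = 0.588). The iron uptake genes FRO2 (0.89), from 94.6 ± 0.929 to 176 ± 0.977 FPKM (SD, n = 2), and CYP82C4 (0.87) rose, and the peptide genes IMA2 (-1.75) and IMA1 (-1.18) fell. After the length correction the same 4 genes had log2 changes of 0.61, 0.84, -1.37 and -0.78, and 10 genes of the list were higher and 6 lower. Of 20 genes of the meristem and the stem cell niche, 8 rose and 4 fell (camera adjusted p = 0.460), and after the length correction the balance turned, to 5 higher and 7 lower, with the median going from 0.06 to -0.08. JKD, a zinc finger gene of ground tissue patterning, rose from 12.8 ± 1.17 to 32.6 ± 0.323 FPKM (SD, n = 2; 1.28, or 1.14 after the length correction), and the root growth factor peptide gene RGF3 was at -0.71, or -0.33 after the correction. In the phloem list 7 of 11 rose and none fell (camera adjusted p = 0.0799, or 0.0294 with a minimum mean of 5 FPKM). The sucrose transporter gene SUC2 went from 6.12 ± 0.379 to 14.1 ± 0.718 FPKM (SD, n = 2; 1.09). Phloem transcripts were long, at a median of 2655 bases, and after the length correction 4 genes were higher and 1 lower, with the median going from 0.23 to 0.03.

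In the main fit of all 4 libraries, without the length correction, the remaining 11 lists did not pass the set test. Other settings gave some of them a call. The abscisic acid list passed with median-ratio scaling (camera adjusted p = 0.0497), a pseudocount of 0.1 FPKM (0.0499) and overlapping and joined lines left out (0.00504). The early stress and touch list passed with quantile normalization (0.0466), and the endodermis list with length and the replicate block (0.0497). Of 6 genes of the abscisic acid and osmotic stress list, 5 fell and 1 rose, a median of -0.50 (camera adjusted p = 0.0508, or 0.0131 after the length correction and then 0.632 with an estimated correlation). With each library left out in turn this list was past the threshold every time (0.0385 to 0.0479), and after the length correction the counts were 5 and 1 again. In the list of early stress and touch genes, 6 of 11 fell and none rose (camera adjusted p = 0.0655), the calmodulin-like gene TCH3 most, from 32.5 ± 0.785 to 14.4 ± 0.563 FPKM (SD, n = 2; -1.12), and after the length correction 4 were lower and 2 higher. In the xylem and secondary wall list 7 of 15 rose and 2 fell, or 7 and none after the length correction (camera adjusted p = 0.108, or 0.0244 after the length correction and then 0.632 with an estimated correlation). Genes that rose and fell numbered 2 and 4 of 12 for the auxin response, 4 and 4 of 11 for endodermis, 2 and 2 of 6 for the root cap, 4 and 4 of 12 for phosphate starvation and 1 and 1 of 6 for jasmonate and defence. They numbered 0 and 1 of 7 for hypoxia, 2 and 0 of 7 for heat shock and 3 and 4 of 8 for the reference genes, with camera adjusted p values over these 8 lists of 0.609 to 0.990. These 8 lists, in the same order, had after the length correction 1 and 2, 8 and 2, 1 and 2, 4 and 1, 2 and 0, 0 and 3, 1 and 2, and 2 and 3 genes higher and lower. Without the correction, counts adjusted over the list alone were the same for these 11 lists.

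**Figure D3:**
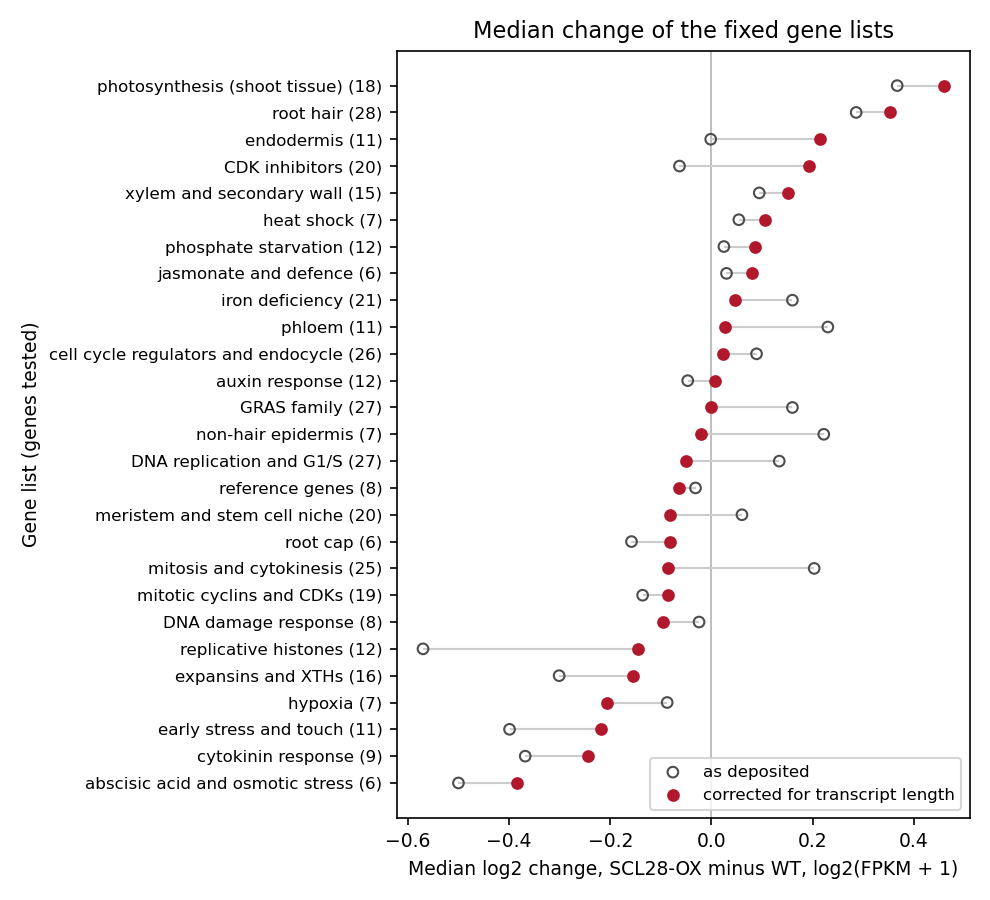
Median log2 change, SCL28-OX minus WT, on the log2(FPKM + 1) scale for the 27 gene lists, as deposited (open circles) and after correction for transcript length (filled circles), with the number of genes tested in brackets. The replicative histones move from -0.57 to -0.15 and the CDK inhibitors from -0.06 to 0.19, while photosynthesis (0.46) and root hair (0.35) have the highest corrected medians.

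With an estimated correlation between genes none of the 27 lists passed camera's threshold. The genotypes were also set against each other in the authors' deposited table, which called 11314 of 19442 tested lines, 5807 with a higher and 5507 with a lower mean in SCL28-OX. Of 18080 genes tested in both, 10771 were called in the same direction by limma and in the authors' deposited table, 1252 by limma alone or in another direction, and 308 in the authors' deposited table alone or in another direction. The odds ratio of the overlap was 161 (Fisher's exact test, two-sided, p at most 1e-300), and Spearman's rho of the log2 changes was 0.9996 across genes, both from the same FPKM values. In the authors' deposited table, SCL28, EXT12, EXT13, SEN1, GSTF14 and IMA2 each had the lowest q-value, 0.000137, which 7077 lines shared.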

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

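The length corrections and the fit without overlapping lines were chosen after the data were seen; the other settings were planned. Of 64 named genes besides SCL28 that were followed, 54 kept their direction and side of the threshold under every setting run for them. Without the length corrections 62 did, and the 2 exceptions were CYCB1;2 and CDKB2;1. MIF3 and the combined line of AT5G24240 and AT5G24250 count among the 54, but lack a transcript length and had no length-corrected fit. SMR3, SMR6 and SMR11, outside the 64, lost their calls after the length correction. The log2 change of SCL28 ranged from 7.59 to 8.33. With each library left out in turn, which leaves a genotype with 1 library assumed to vary like the other 2, 5164 to 5343 genes were higher and 5415 to 5732 lower, 118 to 129 and 76 to 85 of them by at least 2-fold, and 5 to 7 lists were called, the abscisic acid list every time, early stress and touch without WT replicate 2 (0.048), and cytokinin not without SCL28-OX replicate 1. The SCL28 change was then 8.09 to 8.23, and camera adjusted p values were 0.0132 to 0.0296 (GRAS), 0.00986 to 0.0747 (cytokinin), 0.00134 to 0.0053 (photosynthesis), 4.99e-07 to 1.94e-06 (histones) and 0.00427 to 0.0078 (root hair). Replicate numbers do not pair the libraries by the labels, and same-numbered libraries deviated with a correlation of 0.122 over only 2 pairs; with the replicate block, 5793 genes were higher and 6161 lower, and no list call changed.

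The length corrections lowered the counts of called genes: 4009 genes were lower with transcript length, 3719 with coding length, 3979 with length and the replicate block, and 3799 higher and 3559 lower with length and GC. Genes lower by at least 2-fold then numbered 30, 29, 32 and 18. That count also followed the pseudocount, as its construction implies: 212 higher and 159 lower by at least 2-fold at 0.1 FPKM, 44 and 20 at 5 FPKM, and 40 lower with a minimum mean of 5 FPKM, where fewer genes were tested. Under transcript length, coding length, length and GC, and length with the replicate block, the GRAS list lost its call (adjusted p = 0.663, 0.852, 0.535, with its direction turned, and 0.644). In the same order POK2 went to -0.19, -0.21, -0.16 and -0.19, RHS13 to 0.068, 0.013, 0.16 and 0.068, and CDKB2;1 to 0.13, 0.096, 0.073 and 0.13; with each library left out in turn CDKB2;1 lay between -0.078 and 0.025, above 0 without WT replicate 1 (0.0247) and without SCL28-OX replicate 2 (0.0049). The cytokinin list was at 0.284 with coding length and 0.214 with length and GC. Lists called by camera numbered 8 with length and the replicate block and 0 with an estimated correlation (0.576 for 4 of the lists and 0.696 for cytokinin), which the design of 2 libraries per genotype estimates poorly. The 16 lists past the threshold with fry are another kind of call, since fry tests a list against no change and not against other genes. CDKB2;1 was past the threshold at 0.13 under both corrections that give it. The cause of the other changes was not tested. Depth limits low genes: 3 fragments of a 1500-base transcript stand for 0.068 to 0.086 FPKM.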

Other observations

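The groups in this part were formed from the deposited gene descriptions after the data were seen, as were the tests of root hair genes and of library preparation, and the 3 patterns weighed below were themselves noticed in the data. Arabinogalactan protein genes, which encode wall proteoglycans, were mostly higher in SCL28-OX: 31 of 45 rose and 11 fell, with a median log2 change of 0.37, and 33 rose and 4 fell after the length correction, with a median of 0.65 (camera adjusted p over 21 groups = 3.88e-12). Glutathione S-transferase genes were lower, with 42 of 46 falling and 1 rising, and 29 falling and 3 rising after the correction (median -0.18). Of 257 ribosomal protein genes, 230 fell and 11 rose, a median of -0.49; their transcripts are short, at a median of 968 bases, and after the correction 186 fell, 24 rose and the median was -0.16. Kinesin genes showed the opposite end of the length range: 40 of 43 rose at a median length of 3510 bases, and 6 rose and 6 fell after the correction. Cellulose synthase and related genes rose in 18 of 20 cases, and in 11 with 1 fall after the correction (median 0.16). With an estimated correlation none of the 21 groups, extensins included, passed camera's threshold (lowest adjusted p = 0.184, or 0.32 after the correction).

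The log2 change rose with transcript length (rho = 0.68 over genes). GC content is not the whole cause, since within 10 equal groups of genes by GC content the median rho was 0.69 and the lowest 0.462, but the change also rose with GC content (rho = 0.402, and 0.345 after the length correction), so length-corrected values still hold a GC trend. Among the 257 genes described as ribosomal proteins rho was 0.54 (permutation test over genes, two-sided, p = 1e-04, the smallest that 10000 permutations can give). The trend therefore held within this group and not only between groups of genes. These transcripts ran from 349 to 4997 bases, so the group may mix classes, and the test takes genes as independent. Classes of genes that differ in length thus stay open as a part of the cause. All 4 pairs of a WT and an SCL28-OX library showed the trend, with rho of at least 0.659. Within a genotype rho was far smaller, at 0.0415 in WT and -0.0061 in SCL28-OX. RNA integrity or library preparation that differed between the groups cannot be told apart from an effect of the genotype, because each genotype appears as a single block of 2 libraries and the labels give no integrity value or batch.

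By description, extensin and proline-rich genes were higher in SCL28-OX as a family: 25 of 27 rose after the length correction and none fell. The descriptions also take in receptor kinase genes such as PERK1 and PERK10 and leave out HRGP1. The length trend is not the whole cause, since the corrected median log2 change was 1.51 (quartiles 0.90 and 1.82), and reads shared between near-identical copies are not either, since the 25 members with at least 90% unique 50-base words had a median of 1.48. More root hair cells in the sampled tissue would raise other root hair genes alike, but the 23 genes of the root hair list outside this family had a corrected median of 0.25 (quartiles 0.07 and 0.39), too little for the whole rise; 14 of them were higher and none lower, so a larger root hair share stays open for a part of it. A candidate explanation that stays open is a response of these genes to the SCL28 level itself or to any altered growth of the line. A single line and time point do not test it.

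Genes known to be induced in the dark or under sugar starvation were higher in SCL28-OX, with SEN1, DIN10, GAT1_2.1, AT3G15450, DRM2 and ATL8 noticed first. As a hypothesis tested on genes not looked at beforehand, 14 of 18 further markers were expressed. All 14 rose after the length correction, among them TPS8, TPS11, MCCA, GDH2 and BGAL4, with a median log2 change of 0.61. The camera p for this set alone was 2.76e-11, or 0.0194 with an estimated correlation. Neither value was adjusted, so they cannot be set against the adjusted values of the lists and groups above. The libraries were also those in which the pattern was noticed. Without the correction ATG8E was called lower, from 230 to 214 FPKM (-0.11; limma adjusted p = 0.0204). The length trend is not the whole cause, since the lower quartile of the 14 markers after the correction was 0.34. Part of the rise of some markers went with length, as TPS10 moved from 0.63 to 0.15. The GC trend that the correction leaves was not tested for them. The rise of these markers goes with a starvation-like transcript state in the sampled SCL28-OX seedlings. Whether it comes from the genotype or from differences in harvest or growth between the 2 genotypes was not tested. The photosynthesis genes, listed as markers of shoot tissue, rose as well, with 16 of 18 higher after the correction and a median of 0.46. Whether the sampled tissue differed in its share of shoot was not tested.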
